A study of Mus musculus with 108 samples.

How the data were processed

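The data were 108 single-colour arrays (Agilent whole mouse genome oligonucleotide arrays, Cy3) of lung RNA from 36 female mice, 3 arrays per mouse, in 12 groups defined by strain (A/J, B6J, C3H), beam (carbon ions or gamma rays) and treatment (6 h after 10 Gy to the thorax, or unirradiated). Per the labels, RNA was extracted from lung with ISOGEN and an RNeasy kit and labelled with an Agilent Quick Amp kit. The labels name the C3H substrain differently from the design text, so it is called C3H throughout. Per the submitters' processing notes, the arrays were read with Agilent Feature Extraction, whose version is not given in the sources used here. The deposited values are intensities on a linear scale, 1 per feature and array, from 21.1 to 767000 units, with 3 significant digits, and any background subtraction or scaling the authors applied before deposit is not given in the sources used here. The table holds 45018 features numbered between 1 and 45220, and 202 numbers in that range are absent. No file used here pairs these numbers with probes or genes, so the unit of every test was the array feature, the lists of genes fixed in advance (among them p53 targets, cell cycle, inflammation and markers of lung cell types) could not be evaluated, and control spots, if any are among the features, could not be removed.

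Intensities were floored at 1 unit and log2-transformed, and the 75th percentile of each array was subtracted. The near-background threshold was chosen after seeing the data. Because the deposited file has no flags for background or saturation, a level under 1 log2 unit above an array's 25th percentile (median 27.4 units) was called near background, and a fold change with its dimmer side there is given as "at least", counted from that threshold wherever the dimmer group mean of a strain was below it. Features were tested if their highest group mean exceeded the 25th percentile of all scaled values, which removed 3562. Titles carry a pair of numbers for the mouse and the array. Within groups, deviations from the group mean correlated at 0.37 between arrays sharing the first number and at -0.29 between arrays sharing the second, so the first number was taken as the mouse. The 3 arrays of a mouse were averaged before any test (median SD between arrays of a mouse 0.06, between mice of a group 0.16, log2).

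Group means of the 36 mice were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), with 24 residual degrees of freedom shared by all groups and 2.71 prior degrees of freedom, and Benjamini-Hochberg adjustment over the 41456 features of each comparison at a threshold of 0.05. Comparisons were 6 h against control in each strain and beam, their average over strains for each beam, the carbon minus gamma effect, differences of the effect between strains with a moderated F test over the 3 strains, strain differences in unirradiated lung, and carbon against gamma controls. Exact permutation tests were two-sided. The comparisons, the alternatives other than those named as chosen after seeing the data, and the rule for named features (the largest rises and falls by size among called features, with one sign in the 3 strains for the averages over strains) were fixed before the data were examined. Of the features the rule allows, at most 2 in each direction are named, since they carry no gene name. No tested pair of array columns was identical.

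The fit was tested on simulated data made from the measured means and spreads, with 200 of 41456 features changed. For A/J carbon against control it recovered 43.0% of changes of 0.5 log2, 82.0% of changes of 1 and 99.5% of changes of 2. For the average carbon effect it recovered 76.0%, 97.5% and 99.5%, and for the average carbon minus gamma effect 56.5%, 89.0% and 99.5%. With only 200 features changed, the adjusted p sets a stricter cut than in measured comparisons where more features were called. The recovered shares therefore do not carry over to those comparisons. False calls numbered at most 14 in any run. The simulated noise was independent for each feature and mouse, without the deviations that features of a real mouse share. These counts therefore do not measure false calls from such shared deviations. Weights on mice were first estimated by the default REML method of limma, which did not converge, and the gene-by-gene method replaced it after the counts of the first run had been seen. Alternatives covered the scaling (quantile normalization, median centring, no scaling), the filter, the treatment of arrays and mice, the weights, the variance prior, the threshold, the controls used, leaving out each mouse, averaging of features with near-identical profiles, and the brightness of each mouse as a covariate. Because the values are relative to each array's 75th percentile, a change shared by most transcripts would not be seen, and the balance of rises and falls depends on that choice.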

Results

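The series measured gene expression in the lungs of female mice of 3 inbred strains 6 h after local irradiation of the whole thorax with 10 Gy. The strains were A/J, C57BL/6J (labelled B6J) and C3H, and the radiation was either a carbon-ion beam or gamma rays from a caesium source, which served as the reference beam. Each strain and beam had its own 3 irradiated mice and its own 3 unirradiated control mice. Lung RNA from each mouse was hybridised to 3 single-colour arrays, giving 108 arrays from 36 mice in 12 groups. The 75th percentile of intensity ranged over arrays from 10.39 to 10.98 on the log2 scale, and the median intensity from 114 to 217 units. Of 45018 array features, 41456 passed the level filter and were tested, and 27423 of these had a mean level above 2 times the 25th percentile of intensity, which lies near background. The deposited table numbers its features and does not pair them with gene names, so responses are given as numbers of features, as responses of feature sets and, for a few features, by their number on the array. Pathways and cell types could therefore not be assigned to any change below. Each group held 3 mice. The scores over features chosen in other strains, the features called in all 6 comparisons, the partition of the beam difference by control and irradiated lungs, the responses within single experiments and the counts with values as deposited were chosen after seeing the data.

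Strain, experiment and irradiation each left a mark on the lung profiles. Over the features above background, differences between strains held 49.0% of the variance between mice, the difference between the carbon and the gamma experiment 11.1% and irradiation 10.8%. The spread between mice of one group held 19.2%. The first and second principal components, with 29.8% and 19.8% of the variance, parted the strains. The third, with 14.0%, held both experiment and irradiation. Its mean was 37.74 ± 1.62 in carbon controls of B6J and 11.91 ± 7.86 in the gamma controls of that strain, against 5.22 ± 7.13 after carbon and -37.37 ± 5.42 after gamma irradiation (SD, n = 3 mice each). In A/J the gamma controls lay below the mice irradiated with carbon (-13.03 ± 8.87 against 6.20 ± 10.15). In C3H they lay near them (1.53 ± 4.59 against 3.09 ± 7.14), so this component does not separate experiment from irradiation. Unirradiated and irradiated mice are therefore compared below within an experiment.

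**Figure D1:**
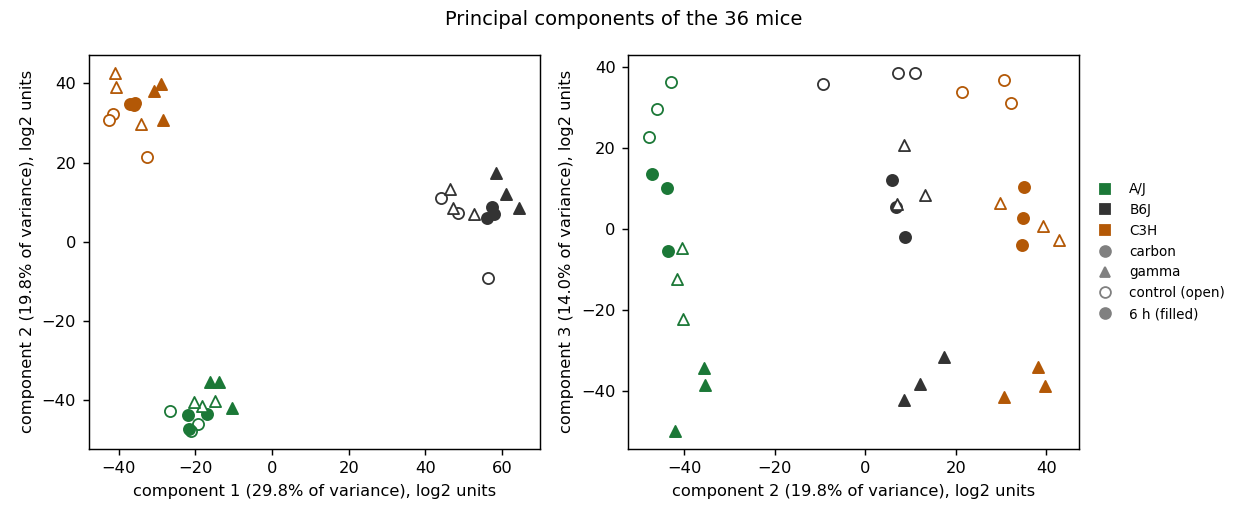
Each point is 1 of 36 mice (mean of 3 arrays), placed by its scores on principal components 1 and 2 (left) and 2 and 3 (right), with colour for strain, circles for the carbon and triangles for the gamma experiment, and open symbols for controls. Strains part along components 1 and 2, which hold 29.8% and 19.8% of the variance, and along component 3 (14.0%) the irradiated mice lie below the controls of their own strain and experiment.

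Irradiation changed the level of many features in every strain and with either beam. With the carbon beam, 1051 features were higher and 888 lower in A/J, 1848 higher and 2024 lower in B6J, and 1139 higher and 839 lower in C3H, each over 3 irradiated and 3 control mice (limma, adjusted p under 0.05). With gamma rays the numbers were 1657 higher and 1544 lower in A/J, 2657 higher and 3465 lower in B6J, and 1802 higher and 1957 lower in C3H. Most changes were small, with a median size among called features between 0.50 and 0.57 on the log2 scale. Changes of at least 2-fold were fewer and leaned upward under carbon in A/J (336 higher, 69 lower) and C3H (236 higher, 71 lower), whereas B6J had 305 higher and 326 lower. After gamma rays, 224 features rose and 153 fell at least 2-fold in A/J, 418 rose and 462 fell in B6J, and 282 rose and 159 fell in C3H.

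The balance of rises and falls depended on the scaling of the arrays. With values as deposited, the carbon numbers became 1236 higher and 330 lower in A/J and 2270 and 1099 in B6J, and the gamma numbers 943 and 1474 in A/J, 1631 and 3535 in B6J and 963 and 2252 in C3H. With arrays centred on their medians, gamma rays gave 2006 higher and 773 lower in A/J and 2108 and 982 in C3H, and carbon 1623 and 1323 in B6J. After quantile normalization, B6J after carbon had 2385 higher and 1984 lower and C3H after gamma rays 2152 and 2117. Leaving out 1 mouse, which leaves 2 in its group, moved several totals by over 1.5 times. Any mouse left out lowered the totals of A/J after carbon (to 1814 at the most), A/J after gamma rays (2615) and C3H after carbon (1882). In B6J after carbon and C3H after gamma rays the highest totals, 3939 and 3868, were above the full ones. A fall therefore does not by itself single out the mouse left out. The total of 1939 in A/J after carbon was 1055 without control mouse 1, 1284 without irradiated mouse 2 and 1261 without irradiated mouse 3, and the 3201 in A/J after gamma rays were 1927 without control mouse 3. The 3872 in B6J after carbon were 2432 without irradiated mouse 3. The 1978 in C3H after carbon were 1082 without control mouse 1, 1183 without irradiated mouse 2 and 1276 without irradiated mouse 3. The 3759 in C3H after gamma rays were 2190 without control mouse 1, 2498 without control mouse 3 and 2471 without irradiated mouse 2. Fitted on their own 6 mice, the comparisons gave 987 features in A/J, 1313 in B6J and 1084 in C3H after carbon, and 922, 3281 and 354 after gamma rays.

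**Figure D2:**
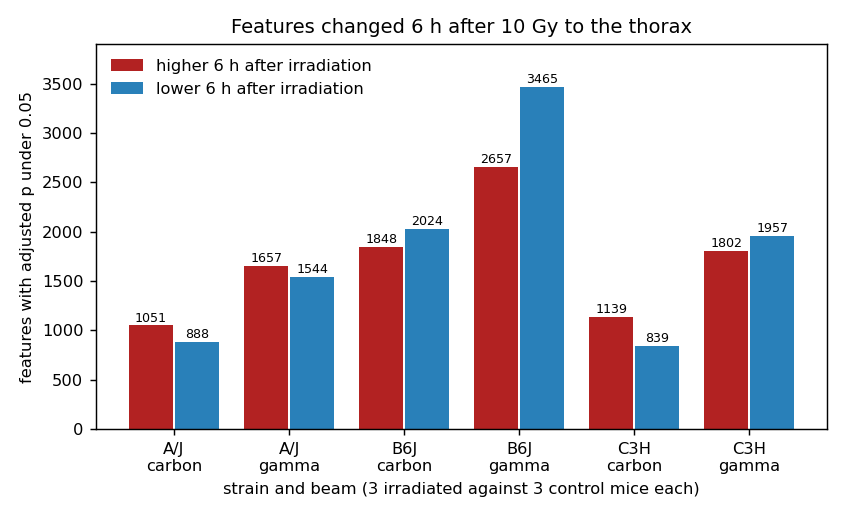
Bars give the number of features higher (red) or lower (blue) 6 h after 10 Gy than in unirradiated controls, at an adjusted p under 0.05, for each strain and beam (3 irradiated and 3 control mice each). The tallest bars are those of B6J after gamma rays, with 2657 features higher and 3465 lower.

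Averaged over the 3 strains, the carbon beam raised 3418 features and lowered 4243. Feature 2168 rose by 4.69 ± 0.09 (log2, SE) with an adjusted p of 1.1e-24 by limma, or 25.8-fold, and was above all controls of its strain in 9 of 9 irradiated mice. Feature 14082, whose controls lay near background in the 3 strains, rose at least 18.3-fold (adjusted p = 2.0e-20) in 9 of 9 mice. Among falls of one direction in all 3 strains, feature 24169 fell by 2.20 ± 0.15 (log2, SE) with an adjusted p of 1.3e-11, and lay below all controls of its strain in 9 of 9 mice. Feature 3346 fell by 1.69 ± 0.28 (adjusted p = 5.2e-05) in 8 of 9 mice. Rises of at least 4-fold numbered 60 and falls of that size 1. With values as deposited, 4042 features were higher and 2356 lower.

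Averaged over the strains, gamma rays raised 4828 features and lowered 6146. Feature 2168 rose at least 27.9-fold (limma adjusted p = 7.1e-25), with controls near background in 2 strains, and feature 14082 at least 12.1-fold (adjusted p = 5.3e-19), with controls near background in the 3 strains, each in 9 of 9 irradiated mice. Feature 16583 fell at least 1.96-fold (adjusted p = 2.4e-12), to near background in the 3 strains. Feature 43583 fell by 1.70 ± 0.13 (log2, SE; adjusted p = 2.0e-10), or 3.24-fold, and both lay below all controls of their strain in 9 of 9 mice. Rises of at least 4-fold numbered 44 and falls of that size 0, while 14955 features had an unadjusted p under 0.05. The balance of calls was 6657 higher and 4066 lower with arrays centred on their medians, and 2655 higher and 7494 lower with values as deposited.

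A common set of features responded in every strain and to either beam. In all 6 comparisons, 390 features were called higher and 126 lower. The median rise of the 390 lay between 0.74 (B6J, gamma) and 0.84 (B6J, carbon) on the log2 scale, and the median fall of the 126 between -0.51 (A/J, carbon) and -0.69 (B6J, gamma). Of the features called for both beams in the strain averages, 2112 were higher with both and 2804 lower with both. Independent lists of those lengths would share 398 and 629, and the beams had separate controls. Calls of opposite direction numbered 105. Across the 27423 features above background the average carbon and gamma effects correlated with a Pearson r of 0.74 and a Spearman rho of 0.58, and features are not independent replicates. Within strains the Pearson correlation between the beams was 0.42 in A/J, 0.54 in B6J and 0.64 in C3H.

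The size of the common response was measured in each strain over features chosen in the other strains. The 542 features called higher under both beams in B6J and C3H rose in A/J by 0.87 after carbon and by 0.86 after gamma rays (log2, SE 0.02 each). The difference between beams was 0.01, with a 95% interval from -0.05 to 0.07. In C3H, the 443 features chosen in the other strains rose by 1.01 and 0.99, a difference of 0.01 with an interval from -0.04 to 0.07. In B6J, the 418 features chosen in A/J and C3H rose by 1.12 after carbon and 1.00 after gamma rays, and the interval of the difference, 0.12, ran from 0.06 to 0.18. The sets chosen for falls moved by -0.43 and -0.53 in A/J (300 features), -0.66 and -0.77 in B6J (153 features) and -0.52 and -0.56 in C3H (210 features), with carbon first. The differences between the beams for these sets were 0.10 in A/J (-0.05 to 0.25), 0.11 in B6J (-0.04 to 0.26) and 0.04 in C3H (-0.10 to 0.18). A two-sided exact permutation test of irradiated against control labels within experiments gave p = 0.005 for each of the 6 sets, the smallest value that its 400 permutations allow.

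The differences between the beams in these scores depended on the scaling, which was varied after seeing the data. For the rising sets in A/J, B6J and C3H they were 0.00, 0.14 and 0.01 after quantile normalization, -0.06, 0.10 and -0.08 with median centring, and 0.15, 0.30 and 0.12 with values as deposited. The B6J interval ran from 0.07 to 0.22, from -0.10 to 0.30 and from 0.06 to 0.53 in these 3 scalings, so that it included 0 with median centring. For the falling sets the differences were 0.07, 0.10 and -0.00 after quantile normalization, 0.03, 0.09 and -0.06 with median centring, and 0.24, 0.29 and 0.14 with values as deposited, where the B6J interval, from 0.01 to 0.56, left out 0. The rises and falls themselves kept their direction and their p of 0.005 under each scaling.

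**Figure D3:**
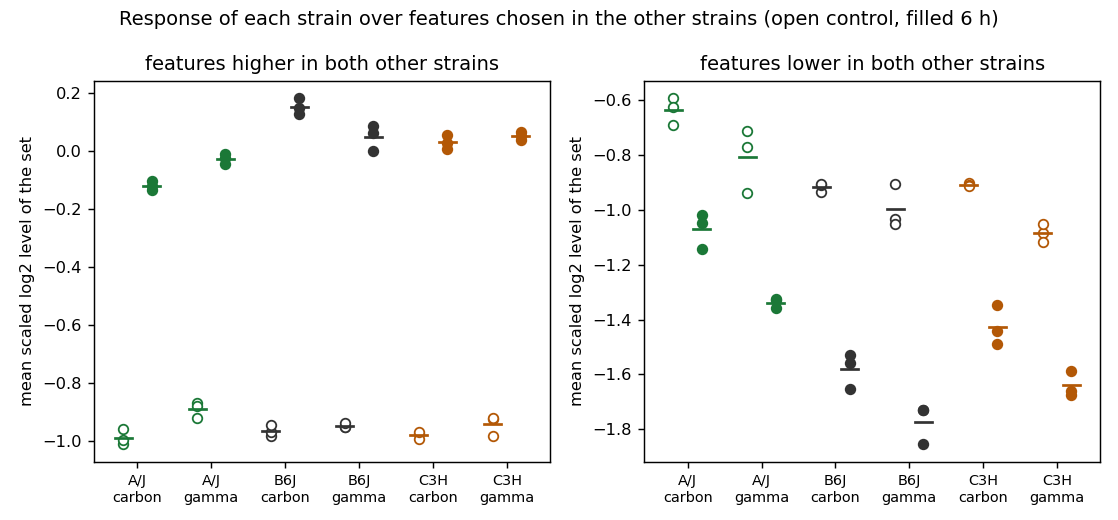
Each point is the mean scaled log2 level, in 1 mouse, of the features that both other strains had called higher (left) or lower (right) after both beams, with open symbols for controls, filled symbols for 6 h after 10 Gy and lines for means of 3 mice. In A/J the 542 features of the left panel rose by 0.87 after carbon and 0.86 after gamma rays, and irradiated mice lie apart from controls in every strain and beam.

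Whether the beams differed at the same physical dose was tested as the carbon effect minus the gamma effect, since each beam had its own controls. Averaged over strains, 613 features had a more positive and 589 a more negative effect under carbon. Across features above background, this difference correlated between B6J and C3H with a Pearson r of 0.44. The r was -0.06 for A/J and B6J and 0.05 for A/J and C3H, so over features as a whole A/J did not share it. Feature 24169 differed most in the negative direction, by -2.47 ± 0.22 (log2, SE; limma adjusted p = 1.4e-07). Its effect was -3.32 in A/J, -1.97 in B6J and -1.30 in C3H after carbon, against 0.10, 0.17 and 0.54 after gamma rays (SE 0.27 each), and the gamma average did not pass the test (adjusted p = 0.20). Its carbon controls also lay below its gamma controls, by -1.60 ± 0.15 (adjusted p = 9.3e-09). Among positive differences, feature 44655 had a fitted value of 2.24 ± 0.28 (adjusted p = 2.8e-05), which includes B6J values near background in the carbon experiment, in both control and irradiated mice. In A/J its effect was 1.02 after carbon and -1.79 after gamma rays, and in C3H 0.83 and -0.59 (SE 0.34 each). Its controls differed by -2.08 between the experiments over the 3 strains, with the same near-background values included. Averaged over strains, its irradiated lungs differed by 0.16 (limma adjusted p = 0.54), so most of its average beam difference lies in its controls. That average covers unlike strains. In A/J the irradiated lungs lay at -3.72 ± 0.26 after carbon and -4.63 ± 0.49 after gamma rays (scaled log2, SD, n = 3 mice). In B6J (-5.25 and -4.92) and C3H (-4.04 and -3.95) those of carbon were the lower.

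Of the 1202 features with a beam difference, 411 had the larger response, in either direction, under carbon. Irradiated lungs of the 2 experiments differed in 580 of them where the controls did not, the controls differed in 270 where the irradiated lungs did not, both differed in 343 and neither in 9. Over all tested features the irradiated lungs differed in 11945. Above background, that difference correlated with the control difference at a Pearson r of 0.75. Features chosen for a beam difference differ in at least 1 of the sets almost by construction, so the partition does not itself show a beam effect. Within single strains, a beam difference was called for 176 features in A/J (87 more positive under carbon, 89 more negative), 140 in B6J (69 and 71) and 55 in C3H (22 and 33). The split by direction was not settled, since the average comparison gave 235 more positive and 482 more negative with arrays centred on their medians, 666 and 676 after quantile normalization, and 1540 and 181 with values as deposited. With values as deposited the split was 203 and 47 in A/J, 204 and 30 in B6J and 38 and 25 in C3H, with median centring it was 42 and 66 in A/J, and after quantile normalization 133 and 92 in B6J. Fitted on its own 4 groups, the comparison gave 32 features in A/J, 11 in B6J and 0 in C3H by limma. In C3H, 1982 features had an unadjusted p under 0.05 by limma. This count was below the share of 0.05 of all tested features that would pass if nothing differed. The 176 features of A/J were 63 without carbon control mouse 1, 114 without gamma control mouse 3, 108 without irradiated carbon mouse 1 and 96 without irradiated gamma mouse 1. The 140 of B6J were 290 without carbon control mouse 3, 228 without irradiated gamma mouse 2, 44 and 55 without irradiated carbon mice 2 and 3, and 72, 55 and 92 without gamma control mice 1, 2 and 3. With the mouse number as a replicate block, B6J had 87.

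**Figure D4:**
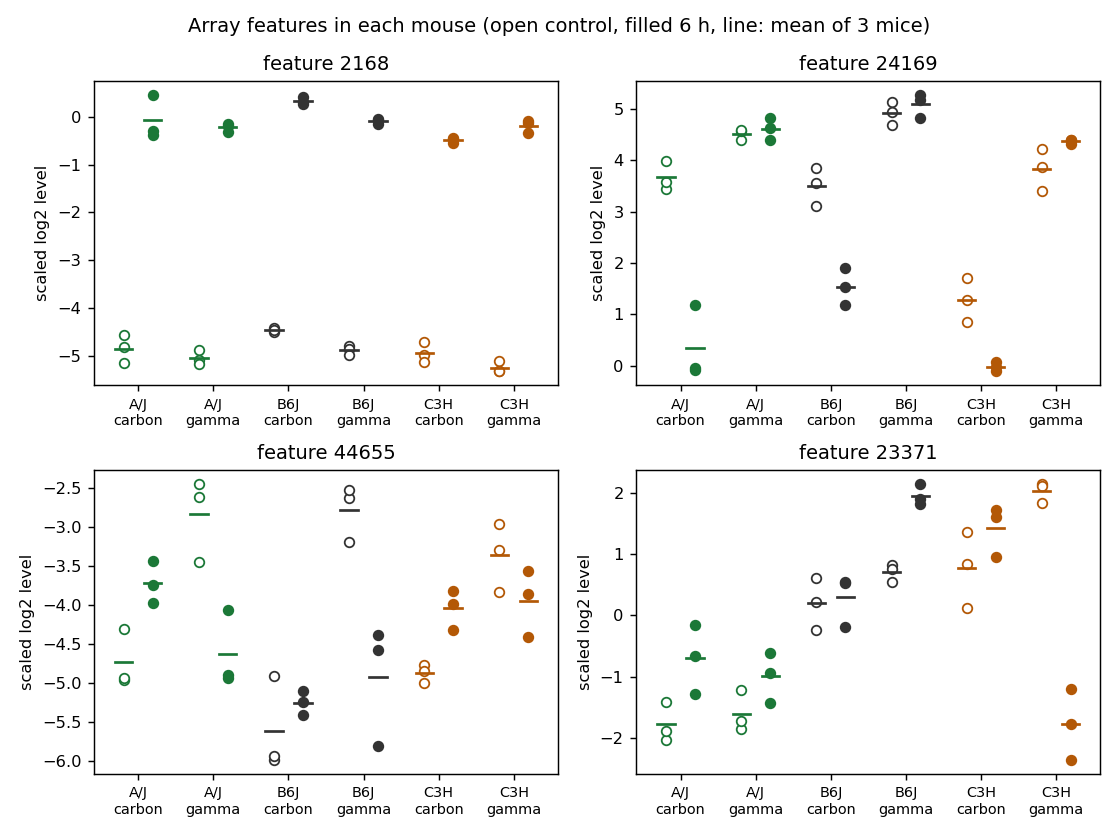
Scaled log2 level of 4 array features in each mouse (open symbols for controls, filled symbols for 6 h after 10 Gy, lines for means of 3 mice), by strain and beam. Feature 2168 rose in each strain with either beam, feature 24169 fell after carbon, feature 44655 started from unlike controls in the 2 experiments, and feature 23371 fell by 3.81 in C3H after gamma rays.

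Whether the strains responded differently was tested on the radiation effect averaged over the beams. A joint test over the strains called 280 features. Between pairs, 250 features differed in response between B6J and A/J (115 more positive in B6J, 135 more negative), 192 between B6J and C3H (74 and 118) and 30 between C3H and A/J (18 more positive in C3H, 12 more negative). Feature 6218 led the higher responses of C3H over A/J, by 1.86 ± 0.32 (log2, SE; limma adjusted p = 0.012), and this came from the gamma experiment. It rose in C3H by 3.66 after gamma rays and its effect was 0.16 after carbon, with 0.15 and -0.05 in A/J after carbon and gamma rays. Feature 23371 led the lower responses, by -2.42 ± 0.32 (adjusted p = 4.7e-04). It fell by 3.81 in C3H after gamma rays, where its effect after carbon was 0.66, and its effects in A/J were 1.08 and 0.61. The difference for feature 6218 was not called with the replicate block, nor with only the groups compared. Neither feature was called with the mouse as a random block over arrays, nor in the carbon experiment alone.

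Within single experiments the pairs that include B6J had fewer differences in response than in the average over beams, and the C3H against A/J pair had more in the gamma experiment. A comparison within 1 experiment rests on fewer mice than the average over beams, so a lower count can come from that alone. The carbon experiment gave 39 features between B6J and A/J, 25 between C3H and A/J and 27 between B6J and C3H, and the gamma experiment 60, 70 and 123. Directions changed with scaling. For B6J against A/J they were 215 more positive and 205 more negative after quantile normalization, and 50 and 95, the same lean as reported, with median centring. For C3H against A/J they were 24 and 30 after quantile normalization, 5 and 10 with median centring and 18 and 27 with values as deposited. For B6J against C3H they were 148 and 130 after quantile normalization and 99 and 72 with values as deposited. Without B6J carbon control mouse 2 the joint test called 450 features and the B6J against A/J pair 446. Without B6J gamma control mouse 1 these were 175 and 111, and the B6J against C3H pair had 125. Without irradiated B6J carbon mouse 3 the pairs of B6J with A/J and with C3H had 136 and 119. The B6J against A/J pair had 131 without B6J carbon control mouse 3, 134 and 150 without A/J carbon control mice 2 and 3, 155 and 135 without irradiated A/J carbon mice 1 and 2, 152 and 134 without A/J gamma control mice 1 and 2, and 156 and 159 without irradiated A/J gamma mice 2 and 3. The C3H against A/J pair had 19 without A/J carbon control mouse 2 and 19 without C3H carbon control mouse 3. With the replicate block the joint test called 153 features and the B6J against A/J pair 114.

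Unirradiated lungs of the strains differed in more features than irradiation changed in any strain. B6J lungs were higher than A/J lungs in 5255 features and lower in 4943, C3H were higher than A/J in 5568 and lower in 6153, and B6J were higher than C3H in 6301 and lower in 5694, with 6 control mice per strain. Differences of at least 4-fold numbered 251 higher and 160 lower for B6J over A/J, 258 and 170 for B6J over C3H, and 118 and 116 for C3H over A/J. With only the carbon controls, 6710 features differed between B6J and A/J and 7487 between C3H and A/J. The direction of these splits depended on the scaling. For B6J against A/J the split was 5222 higher and 5657 lower after quantile normalization, 3915 and 5522 with median centring, and 5934 and 3352 with values as deposited. For B6J against C3H it was 6312 and 6595 after quantile normalization and 4840 and 6215 with median centring, and for C3H against A/J 5447 and 4771 with values as deposited.

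Controls of the carbon and the gamma experiment, neither of which was irradiated, differed in 9199 features averaged over the strains, 4373 higher in carbon controls and 4826 lower. Within strains the numbers were 3892 in A/J, 1788 in B6J and 5679 in C3H. Across features above background these control differences correlated between strains with a Pearson r of 0.58 for A/J and B6J, 0.40 for A/J and C3H and 0.66 for B6J and C3H. The Spearman rho were 0.62, 0.46 and 0.63. By size, 186 features were at least 2-fold higher and 155 lower in carbon controls, 4 higher and 30 lower at 4-fold, 3 and 2 at 8-fold and 0 and 2 at 16-fold. With median centring, 2864 features were higher and 5659 lower.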

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

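Among the tests in this part, those of the control sets, of the scaling of the arrays in each pattern, of the share of higher features in single strains and of the main axis of deviation were chosen only after the result was seen. The tests of scaling for the first and second pattern were widened to median centring after narrower ones, without it, had given 1342 features and a ratio of 1.75. The brightness test was added after the splits below had been seen. In some groups all arrays of 1 mouse were dimmer at the 75th percentile of intensity than the arrays of the other mice. The widest gaps of this kind were those of mouse 2 of C3H 6 h after gamma rays (1340 to 1480 against 1660 to 1930 units), mouse 1 of A/J 6 h after gamma rays (1370 to 1460 against 1680 to 1810) and mouse 2 of the B6J carbon controls (1450 to 1500 against 1780 to 1940). They also had the lowest weights of the 36 mice (0.0794, 0.117 and 0.0742).

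Differences between groups in the response to irradiation drew attention. Averaged over strains, 1202 features responded differently to the beams, with 176 in A/J, 140 in B6J and 55 in C3H. The strains differed in 280 features in the joint test, with 250 between B6J and A/J, 30 between C3H and A/J and 192 between B6J and C3H. Single features among them were 44655, whose carbon effect exceeded its gamma effect by 2.24 with B6J values near background included, 24169 with a difference of -2.47, 6218 with a C3H minus A/J response of 1.86 and 23371 with -2.42 (log2). For feature 44655 the controls of the 2 experiments differed by -2.08 and the irradiated lungs by 0.16, averaged over strains.

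Other splits of the same mice bear on chance. With 3 mice against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1939, 3201, 3872, 6122, 1978 and 3759 features for A/J, B6J and C3H (carbon, then gamma rays in each), and the highest of the other splits 9, 13, 1, 13, 16 and 85, so that 1 of 10 splits was as large in each. Of 100 splits, 1 was as large as the real one, the real one itself, for the average carbon effect (7661 features, highest other 319), the average gamma effect (10974 and 8323), the beam difference in A/J (176 and 25), B6J (140 and 20) and C3H (55 and 4), the response of B6J against A/J (250 and 3) and of C3H against A/J (30 and 14), the unirradiated strain pairs B6J against A/J (10198 and 7788), C3H against A/J (11721 and 7288) and B6J against C3H (11995 and 5593), and carbon against gamma controls (9199 and 4495). This argues against chance assignment for these, at the smallest share that 100 splits allow. The share was also under 0.05 for 3 other comparisons. It was 2 of 100 for the average beam difference (1202, highest other 9027) and the response of B6J against C3H (192 and 6336). For the joint strain test it was 3 of 100 (280 and 13633). No share was corrected for the number of comparisons, so for these 3 chance is made less likely and is not excluded. Splits with several times the real count point to a structure among the mice. In these 3 comparisons the split with the highest count ranked 1 of the other splits in its contrast along the main axis of deviation of mice from their group means, an axis that correlated with array brightness (Pearson r = 0.86). Over all of the other splits, the count followed that contrast weakly, with a Spearman rho of 0.18 for the average beam difference, 0.27 for the joint strain test and 0.01 for B6J against C3H. The highest splits of the average gamma effect, of the B6J against C3H controls and of carbon against gamma controls ranked 56, 68 and 71. Those of the B6J and C3H controls against A/J controls (7788 and 7288) ranked 9 and 16. Rank 1 was also found for A/J carbon and the A/J beam difference, whose highest other counts were 9 and 25. The axis therefore goes with the highest counts of the 3 comparisons that other splits exceeded, and not with high counts in every comparison. What the structure is stays open.

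The first pattern is the set of 1202 features with a different response to the beams. Leaving out any 1 of the 36 mice left at least 866 features, which argues against a single mouse as the whole cause. With the brightness of each mouse as a covariate 1371 were called. Whether these include the 1202 was not tested. The covariate also moved 10 of 20 counts well up and 0 well down. Irradiated minus control brightness was 0.08, 0.11 and -0.004 log2 after carbon (A/J, B6J, C3H). After gamma rays it was -0.06, -0.06 and -0.11, lower than after carbon in each strain. The count therefore cannot decide, and array brightness stays open. The scaling of the arrays stays open for a part, since the lowest count over 3 other scalings, that of median centring, was 717, between the bounds set for the test, and the direction of the differences changed with it. A difference between the control sets also remains open, since 34.9% of these features differed more between the control sets than between the irradiated sets. The controls themselves differed in 613 of the 1202. Each beam was its own experiment, so for none of these features can an effect of the experiment on the response be told apart from the beam. A change limited to the irradiated mice of an experiment, such as handling, was not tested and stays open beside a difference in radiation quality.

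The second pattern is the larger number of calls after irradiation in B6J, 1.84 times the mean of A/J and C3H over both beams (9994 against 5140 and 5737). A feature called under both beams counts in each. Among 21708 features whose unirradiated levels lay within 0.25 log2 in the strains, the ratio was 1.88, which argues against sequence variants under the probes as its cause. Over 3 other scalings it was 1.75 at the least, which argues against the scaling. With each strain fitted alone over both beams it was 1.82. Fitted on their own 6 mice, the carbon comparisons gave 1313 calls in B6J against 987 in A/J and 1084 in C3H. The gamma ones gave 3281 against 922 and 354. This argues against a wider spread of B6J mice hidden by the shared estimate for gamma rays, and leaves it open for carbon. Leaving out 1 B6J mouse lowered the ratio over both beams to 1.48 at the least, under the 1.5 set as the bound before the test. The A/J and C3H counts kept all their mice there, so the ratio also carries the loss of a mouse from B6J alone. The test therefore cannot decide, and a contribution of single mice stays open. A stronger response of this strain stays open as a hypothesis, with 250 and 192 features differing from A/J and C3H when the difference itself was tested.

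The third pattern concerns features at least 4-fold apart in 1 strain before irradiation while the other strains lay within 0.5 log2. B6J was higher in 65.7% of its 207 such features (exact binomial 95% interval 58.8 to 72.1), A/J in 33.9% of 59 (22.1 to 47.4) and C3H in 44.2% of 77 (32.8 to 55.9), the intervals covering counting error alone. Probes drawn from the sequence of B6J may bind the transcripts of other strains less well, which would place B6J above and both others below 50%. The C3H interval includes 50, so this cannot be told apart from differences in expression. After quantile normalization the B6J share was 64.4%, which argues against scaling as the cause.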

How the results depend on the processing

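The alternatives chosen only after the data were seen were the values as deposited, the averaging of near-identical features, the restriction to features above 2 times the 25th percentile, the single-experiment responses the brightness covariate, the method for weights and the scalings of the scores over chosen features. Of 358 counts under other settings, 204 lay within 1.5 times the reported count. The counts of the average carbon and gamma effects stayed within that range under all 3 changes of scaling, and all 20 did so without a filter, with a trended prior and with near-identical features averaged (983 features in 108 sets). Across their alternatives the named features kept their direction, and those of the carbon, gamma and beam comparisons kept their calls. For the C3H against A/J response, feature 6218 was no longer called under 5 of 43 alternatives and feature 23371 under 2 of 43. Scaling moved the median difference of all features by over 0.1 log2 in places, at most by 0.19 for the B6J beam difference with values as deposited. Signal over background limits the calls, since 3110 of 3418 rises and 3800 of 4243 falls of the average carbon effect lay above 2 times the 25th percentile. The gene-level alternatives and those of the gene lists were not run, since features have no gene names. Weights on mice by limma's default method did not converge, and the gene-by-gene method replaced it after the first counts had been seen.

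Quantile normalization gave 225 for B6J beam difference, 89 for C3H beam difference, 493 for joint strain test, 420 for B6J against A/J response and 54 for C3H against A/J response. Centring on medians gave 717 for mean beam difference, 108 for A/J beam difference, 55 for B6J beam difference, 33 for C3H beam difference, 183 for joint strain test, 145 for B6J against A/J response, 15 for C3H against A/J response and 119 for B6J against C3H response. Values as deposited gave 234 for B6J beam difference. The 50th-percentile filter gave 15 for C3H against A/J response, and features above 2 times the 25th percentile 17 for C3H against A/J response. Only the groups compared, with fewer mice in the estimate of spread, gave 987 for A/J carbon, 922 for A/J gamma, 1313 for B6J carbon, 3281 for B6J gamma, 1084 for C3H carbon, 354 for C3H gamma, 32 for A/J beam difference, 11 for B6J beam difference, 0 for C3H beam difference and 127 for B6J against A/J response. Brightness as a covariate gave 3518 for A/J carbon, 5365 for A/J gamma, 3551 for C3H carbon, 649 for A/J beam difference, 314 for B6J beam difference, 106 for C3H beam difference, 694 for joint strain test, 679 for B6J against A/J response, 84 for C3H against A/J response and 397 for B6J against C3H response. Controls of both beams together gave 5328 for A/J gamma, carbon controls alone 6710 for B6J against A/J controls and 7487 for C3H against A/J controls, the carbon experiment alone 39 for B6J against A/J response and 27 for B6J against C3H response, and the gamma experiment alone 60 for B6J against A/J response, 70 for C3H against A/J response and 123 for B6J against C3H response. For these settings the cause was not tested unless stated.

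The replicate block, which pairs irradiated and control mice of one number, gave 87 for B6J beam difference, 153 for joint strain test and 114 for B6J against A/J response, and moved no other count by over 1.5 times. The deviations of same-numbered mice correlated between -0.31 and 0.41, with 7 of 18 pairs above 0.1. In A/J the 6 pairs were positive, between 0.10 and 0.41, while B6J and C3H had pairs of either sign. Of 36 mice, 14 correlated best with their own number, so the mice were taken to share only a number.

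All 9 arrays of a group taken as independent, a random mouse block over arrays, the second number taken as the mouse, weights on mice and the thresholds change the counts by construction or, for the weights, for a cause that was not tested. The order in each list is A/J carbon, A/J gamma, B6J carbon, B6J gamma, C3H carbon, C3H gamma, mean carbon, mean gamma, mean beam difference, A/J beam difference, B6J beam difference, C3H beam difference, joint strain test, B6J against A/J response, C3H against A/J response, B6J against C3H response, B6J against A/J controls, C3H against A/J controls, B6J against C3H controls and carbon against gamma controls. With 9 independent arrays the counts were 9428, 12341, 14485, 15349, 10141, 18077, 20037, 24602, 18675, 6755, 12107, 5203, 9037, 5864, 3175, 5983, 17996, 20253, 20352 and 17866. With the second number as the mouse, which averages over mice, they were 24512, 24506, 27262, 27544, 20462, 28463, 28867, 31013, 28336, 23197, 26000, 24036, 28066, 17744, 20903, 23846, 29244, 29317, 25760 and 27721. With weights they were 9594, 9707, 11982, 18597, 3590, 11440, 14492, 18061, 6157, 5062, 5952, 846, 6593, 7657, 861, 3181, 22305, 17979, 17784 and 14381. With a difference of at least 1 log2 they were 405, 377, 631, 880, 307, 441, 347, 384, 75, 74, 48, 30, 65, 50, 12, 44, 1589, 1213, 1803 and 341. At an adjusted p under 0.01 they were 1010, 1559, 2069, 3580, 882, 1692, 4927, 7418, 392, 47, 37, 29, 90, 64, 11, 61, 7335, 8156, 8819 and 6190. The random block gave 3469 for A/J carbon, 5423 for A/J gamma, 6107 for B6J carbon, 3933 for C3H carbon, 7092 for C3H gamma, 4039 for mean beam difference, 1606 for A/J beam difference, 1228 for B6J beam difference, 289 for C3H beam difference, 1965 for joint strain test, 1523 for B6J against A/J response, 415 for C3H against A/J response and 997 for B6J against C3H response.

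Leaving out 1 mouse in turn moved 40 of 306 counts by over 1.5 times, and the ranges were 1055 to 1814 for A/J carbon, 1927 to 2615 for A/J gamma, 2432 to 3939 for B6J carbon, 1082 to 1882 for C3H carbon, 2190 to 3868 for C3H gamma, 63 to 224 for A/J beam difference, 44 to 290 for B6J beam difference, 175 to 450 for joint strain test, 111 to 446 for B6J against A/J response, 19 to 38 for C3H against A/J response and 119 to 247 for B6J against C3H response. Where this left 2 mice in a group, the spread was shared with the other groups. A lower count can come from the smaller group alone.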

Other observations

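All tests in this part were chosen only after the result was seen. Deviations of mice from their group means followed the brightness of their arrays. Across the 36 mice, the deviation from the group mean along their main axis, which held 30.8% of the deviations, correlated with the deviation in the 75th percentile of intensity (Pearson r = 0.86, permutation p = 4.7e-04; Spearman rho = 0.79, permutation p = 3.9e-04; 100000 permutations within groups, 2 relations computed). Without the 2 mice farthest from the median brightness r was 0.77, with 1 of the 3 dim mice still in. Irradiated groups differed from their controls in brightness by 0.08, 0.11 and -0.004 log2 in the carbon experiment (A/J, B6J, C3H) and by -0.06, -0.06 and -0.11 in the gamma experiment.

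Feature 24169, chosen here after its values were seen, was the only one to fall at least 4-fold in the average carbon effect. Its mean level fell from 3.67 ± 0.28 to 0.35 ± 0.73 in A/J, from 3.50 ± 0.38 to 1.54 ± 0.36 in B6J and from 1.28 ± 0.43 to -0.02 ± 0.09 in C3H after carbon (scaled log2, SD, n = 3 mice). In the gamma experiment it was 4.51 ± 0.11 and 4.62 ± 0.21 in A/J, 4.92 ± 0.22 and 5.09 ± 0.24 in B6J and 3.83 ± 0.41 and 4.37 ± 0.05 in C3H, control first.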
